A study of Oryza sativa with 36 samples.

How the data were processed

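Gene expression was measured by RNA sequencing of flag leaves from the super-hybrid rice WFYT025 and its parents, WFB and CHT025. Leaves of each variety came from day 1 and day 10 after flowering, in a crop grown as early rice and one grown as middle rice, which are called the early and the middle season here. The labels name 3 replicates for each of the 12 combinations of variety, day and season, which gives 36 libraries. Per the labels' protocols, total RNA was extracted with Trizol, mRNA was fragmented and reverse-transcribed, and paired ends were sequenced. The labels do not say whether the replicates came from separate plants, so p-values measure only the spread between these libraries, which may be technical.

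The authors deposited 6 tables, each holding the day 1 and day 10 libraries of one variety in one season. Per the file headers, the values are FPKM (fragments scaled by transcript length and by the mapped fragments of the library), written with 2 decimals, 1 column per library. HISAT, StringTie and edgeR are named in the submitters' processing notes; their versions, the genome build and the annotation are not given in the sources used here. The same tables carry the authors' deposited log2 ratio of each gene, which was found to be day 1 over day 10, with the authors' p-value and q-value. Only read counts would show the depth, so the depth of the libraries is unknown and no counting interval is given. The early-season table of WFYT025 starts over inside itself: it has 1 broken line and 49538 complete ones, of which 7534 recur unchanged, and the broken and recurring lines were dropped. It then lists 42004 genes, 7381 more than the other tables, and all of those extra genes have an FPKM of 0. The 34623 genes common to all tables were used. Of 24 housekeeping loci, 4 were listed at 0 in some library, so a 0 is reported only as listed at 0.

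The FPKM sum per library ran from 532276 to 567391, genes above 0 from 21656 to 23811, and the 10 most abundant genes took 12.7% to 16.9% of the sum. Across pairs of libraries of one group, Pearson's r of log2(FPKM + 1) was 0.9902 to 0.9956, with a median of 0.9938, against 0.7943 to 0.976 between groups (correlations across genes, which are not independent replicates). The median log2(FPKM + 1) of the tested genes differed between groups, from 2.65 in WFYT025 on day 1 of the middle season to 3.07 in CHT025 on day 10 of the middle season. All values were used as deposited. Quantile normalization of the libraries removes such shifts. Where it moved the share of higher genes among all called genes by more than 10 percentage points, that split stands beside the main one; for the gene lists such splits are given for part of the cases only.

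Genes with at least 1 FPKM in at least 3 libraries were tested, 18585 in all. Log2(FPKM + 1) was fitted with limma 3.58.1 (R 4.3.3) as 12 group means over all 36 libraries, with moderated two-sided tests, an intensity trend and Benjamini-Hochberg adjustment over the tested genes. A gene was called at an adjusted p under 0.05. The fit had 24 residual degrees of freedom, and the median residual SD was 0.106 on the log2 scale, so small changes were called. The number of genes changed at least 2-fold is therefore given with the count of called genes for each comparison. All fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values, and each is given as log2 with its standard error or as group means ± SD (n = 3). Files were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

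The comparisons were day 10 against day 1 for each variety and season, WFYT025 against each parent and against the mean of both parents on the log2 scale (mid-parent), the middle against the early season averaged over both days, and the season difference of the change from day 1 to day 10. Genes called in the same direction against each parent were counted as outside both parents. The comparisons, the tests, the gene lists, the rule for named genes and all alternatives except those said to be chosen later were fixed before the data were examined.

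Tested on simulated data, with 100 of the 18585 genes changed at each size, the fit recovered 93% of 1.5-fold and 96% of 2-fold changes for day 10 against day 1 in WFB in the early season, with 10 false calls. For the mid-parent comparison of day 1 in the early season it recovered 94% and 95%, with 13 false calls. For the season comparison of WFB it recovered 97% and 100%, with 10 false calls. For the season difference of the day change in WFB it recovered 70% and 90%, with 7 false calls.

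The 17 gene lists cover light reactions, carbon fixation and photorespiration, chlorophyll synthesis, chlorophyll breakdown and leaf senescence, nitrogen assimilation and remobilisation, sucrose synthesis and export, starch synthesis and turnover, circadian clock and flowering time, heat shock and protein folding, antioxidant enzymes, defence, abscisic acid and dehydration, ribosome, cell division, proteasome, grain tissue markers, and root and stomatal guard cell markers. They were made from loci written by hand (143, of which 141 are in the tables) and from annotation terms that the deposited tables pair with genes. Lists of at least 5 tested genes were tested with camera, limma's competitive gene set test, at a preset correlation of 0.01 and again with an estimated correlation. Camera asks whether a list moves relative to the other genes, so its direction can differ from the sign of the list's median. Counts over all genes stand beside those "adjusted over the list alone" where the latter differ. Enrichment of annotation terms of 10 to 500 genes was tested among called genes with Fisher's exact test, against the 15846 tested genes with any term.

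Loci are given as the files name them. Symbols come from the list loci, and descriptions come from the files; a reference table of gene names matched 0 of the identifiers, and no coordinates were used. Named genes needed a symbol or an informative description. For the day comparison they were the 10 highest and 10 lowest by mean log2 among genes called in 1 direction and changed at least 2-fold in 5 of 6 comparisons (8 genes fell by that rule). For the hybrid they were the 6 highest and 6 lowest of those called in 1 direction against the mid-parent in all 4 settings, with, in each setting, the 3 genes farthest above and the 3 farthest below both parents. For the season and for the season difference of the day change they were the 8 and the 5 highest and lowest of those with 1 direction in all 3 varieties. From the lists, up to 2 called members per direction with the largest change were taken, with RBCS2, RCA, CAB1R, OsNAP, SGR, NYC1, Hd3a, SUT1 and GluA1 added in any case. In addition to these, 1 further gene was set to be named in any case and is not reported here.

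The alternatives tried were a pseudocount of 0.1, no filter, quantile normalization, a replicate block, the libraries of each comparison alone, an arithmetic mid-parent, camera with an estimated correlation and leaving out each library in turn. Those chosen after seeing the data were the season comparison within each day, quantile normalization for the annotation terms, and the level of grain storage transcripts as a covariate.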

Results

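The data describe the transcriptome of the flag leaf, the uppermost leaf, which supplies most of the sugar to the filling grain. The 36 libraries come from the hybrid WFYT025 and its parents WFB and CHT025 on day 1 and day 10 after flowering, in the early and the middle season, with 3 libraries per group. The design asks how the flag leaf changes during the first days of grain filling, how the hybrid differs from its parents, and how both depend on the season. Season stands for everything that differed between the crops, including any batch of sampling or sequencing that went with it. Such a batch and the season cannot be told apart.

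Between day 1 and day 10, a small number of genes moved in 1 direction in nearly all varieties and seasons, while many large changes differed between the seasons. An ammonium transporter gene (LOC_Os03g62200) rose in all 6 comparisons. In WFYT025 of the middle season it went from 2.64 ± 0.622 FPKM to 105 ± 6.39 (n = 3; log2 4.87 ± 0.13, adjusted p = 8.07e-24), and in WFB of that season from 6.81 ± 0.156 to 62.9 ± 8.8. OsNAP, a NAC transcription factor that promotes leaf senescence, also rose in all 6, from 10.6 ± 0.66 to 46.7 ± 2.56 FPKM in WFB of the middle season (log2 2.05 ± 0.08, adjusted p = 1.21e-19). A transcript with a conserved upstream open reading frame (LOC_Os05g47540) fell in all 6, from 228 ± 9.3 to 20.9 ± 1.14 FPKM in WFB of the early season (log2 -3.39 ± 0.14, adjusted p = 1.51e-19).

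Other genes that rose in all 6 comparisons were a transporter gene (LOC_Os03g10100), by log2 1.35 to 3.59, another (LOC_Os10g41190), by 0.99 to 2.33, and a DUF588 membrane protein gene (LOC_Os03g10030), by 1.42 to 2.74. An aldo/keto reductase gene (LOC_Os04g37490) rose by 0.35 in WFB and 4.03 in WFYT025, both in the middle season, and a further transporter gene (LOC_Os07g39350) rose from 41 ± 1.37 to 351 ± 5.6 FPKM in WFYT025 of the middle season. The calcium sensor OsCML21 (LOC_Os05g24780), the glutathione S-transferase GSTU6 (LOC_Os10g38489), a glycerophosphoryl diester phosphodiesterase gene (LOC_Os02g31030) and an amino acid transporter gene (LOC_Os12g09300) each rose in 5 of the 6. OsCML21 was not called in WFB of the early season, where it was listed at 0 on day 1 (adjusted p = 0.0787), and the remaining values of the others were 0.03 (0.797), 0.26 (0.095) and -0.01 (0.95). Among the genes that fell in all 6 were a peroxidase gene (LOC_Os07g48010), with log2 between -3.27 and -0.90, and an alpha-galactosidase gene (LOC_Os10g35110), with log2 between -2.27 and -0.43. An osmotin gene (LOC_Os12g38170) and LTPL124 (LOC_Os04g52260) fell in 5 comparisons and rose in 1, by 1.02 in WFYT025 and by 1.16 in WFB, both in the early season. A membrane protein gene (LOC_Os08g30020), a protein phosphatase 2C gene (LOC_Os01g46760) and an aldo/keto reductase gene (LOC_Os07g04990) fell in 5, and their other values were 0.20 (adjusted p = 0.209), 0.23 (0.0684) and -0.07 (0.159).

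In the early season, limma called 4654 genes higher and 8562 lower on day 10 in WFB, 4662 and 7422 in CHT025, and 6130 and 6509 in WFYT025. In the middle season it called 8555 higher and 3827 lower in WFB, 4301 and 3802 in CHT025, and 8863 and 3079 in WFYT025. Changes of at least 2-fold numbered 1326 higher and 1943 lower in WFB, 626 and 1204 in CHT025, and 1116 and 1151 in WFYT025 in the early season. The middle season gave 955 and 829, 307 and 406, and 1472 and 305. After quantile normalization the 2-fold splits were 1560 and 1493 in WFB and 853 and 953 in CHT025 of the early season, and 712 and 982 in WFB and 1109 and 613 in WFYT025 of the middle season. The same normalization gave splits of all called genes of 6148 higher and 6602 lower in WFB and 6320 and 5621 in CHT025 in the early season. Those of the middle season were 6078 and 4897 in WFB and 4348 and 6602 in WFYT025, so the balance between directions depends on the scaling. The median log2 change of all genes was -0.15 in WFB of the early season and 0.18 in WFYT025 of the middle season. In the authors' deposited tables, 1801 genes were significantly higher on day 10 and 3336 higher on day 1 in WFB of the early season. The numbers there were 1143 and 1952 for CHT025 and 1918 and 1839 for WFYT025, and in the middle season 1954 and 1278, 616 and 896, and 2226 and 725 in the same order.

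**Figure D1:**
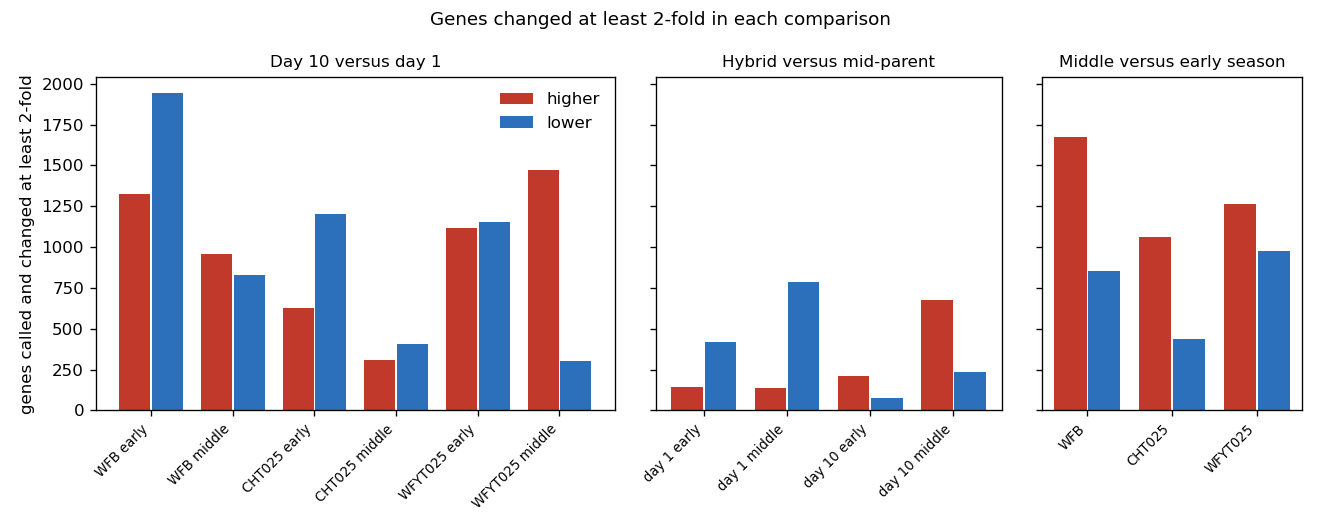
Bars give the number of genes (linear axis from 0) called by limma and changed at least 2-fold, higher in red and lower in blue, for day 10 against day 1 in each variety and season, for the hybrid against the mid-parent, and for the middle against the early season. The lower bar of WFB in the early season reaches 1943 genes, and in WFYT025 of the middle season 1472 genes were higher and 305 lower; after quantile normalization these were 1493, 1109 and 613.

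Ribosomal protein genes fell on day 10 in all 3 varieties in the early season. Of the 336 genes annotated as structural constituents of the ribosome, 255 fell and 39 rose in WFB (256 fell when adjusted over the list alone), 251 fell and 30 rose in CHT025 (253), and 269 fell and 33 rose in WFYT025 (270 and 34). Camera adjusted p-values were 3e-06, 7.92e-09 and 1.53e-16. With an estimated correlation they were adjusted p = 0.138, adjusted p = 0.0508 and adjusted p = 0.00353, so the call was kept in WFYT025. Among the large falls were a plastid 30S protein gene (LOC_Os03g63950; log2 -3.28, -4.24 and -2.80), a plastid 50S protein gene (LOC_Os11g34940) in WFB (-3.72) and an L7/L12 gene (LOC_Os05g49320) in WFYT025 (-2.89). In the middle season 177 fell and 15 rose in CHT025 (183 and 16 adjusted over the list alone; camera adjusted p = 9.08e-10, and adjusted p = 0.0287 with an estimated correlation). There 141 rose and 52 fell in WFB (140 rose adjusted over the list alone), and 124 rose and 28 fell in WFYT025 (121 and 27), with no camera call (adjusted p = 0.874 and 0.446). After quantile normalization 38 rose and 159 fell in WFYT025 of that season, so its direction depends on the scaling.

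Chlorophyll synthesis genes fell on day 10 in WFYT025 of the early season, where 18 of 24 fell and 3 rose (camera adjusted p = 0.000116, and adjusted p = 0.00353 with an estimated correlation). In CHT025 of the middle season 13 fell and 4 rose (14 fell adjusted over the list alone; camera adjusted p = 0.000228, and adjusted p = 0.0091 with an estimated correlation). PORA, the light-dependent protochlorophyllide reductase of greening tissue, fell in the early season in all varieties, from 691 ± 54.1 to 87.5 ± 3 FPKM in WFB (log2 -2.97), and its relative PORB fell from 534 ± 19.5 to 225 ± 7.2. CHLD, a subunit of magnesium chelatase, changed by log2 -1.16 in WFB of the early season and 0.16 in the middle season. In WFB of the early season 19 genes of the list fell and 2 rose (20 fell adjusted over the list alone; camera adjusted p = 0.00324, but adjusted p = 0.0633 with an estimated correlation). In WFYT025 of the middle season 12 fell and 8 rose (0.00831, but adjusted p = 0.137 with an estimated correlation). In WFB of the middle season 15 rose and 6 fell (16 rose adjusted over the list alone), without a camera call (adjusted p = 0.562). In CHT025 of the early season 13 fell and 5 rose (15 fell adjusted over the list alone), also without one (0.182).

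Of the 59 light reaction genes, 36 fell and 2 rose in CHT025 of the middle season (37 and 3 adjusted over the list alone), and 35 fell and 8 rose in WFYT025 of the middle season (36 fell adjusted over the list alone). In WFYT025 of the early season 36 fell and 15 rose. Camera called these lists (adjusted p = 1.48e-08, 3.74e-10 and 0.00128). With an estimated correlation none of the calls was kept (adjusted p = 0.0893, adjusted p = 0.169 and adjusted p = 0.309). The members moved apart: the early light-induced protein gene LOC_Os07g08160, of a family that protects against excess light, rose from 2.28 ± 0.745 to 343 ± 6.41 FPKM in WFB of the early season (log2 6.74). A chlorophyll a/b binding protein gene (LOC_Os09g26810) fell by 3.66 on the log2 scale in that comparison. In WFB 34 members fell and 18 rose in the early season and 19 fell and 21 rose in the middle season, and in CHT025 of the early season 37 fell and 14 rose, without a camera call. RBCS2, a small subunit of the CO2-fixing enzyme Rubisco, fell in the middle season by 0.87 in WFB, 0.62 in CHT025 and 1.23 in WFYT025 on the log2 scale. RCA, Rubisco activase, rose in the early season from 5303 ± 33.6 to 15912 ± 610 FPKM in WFB (log2 1.58). CAB1R, an abundant chlorophyll-binding protein gene, stood between -0.45 and 0.24, and its value of -0.02 in WFYT025 of the middle season became 0.42 after quantile normalization. Of the 41 carbon fixation and photorespiration genes, 12, 17 and 11 rose and 18, 12 and 19 fell in WFB, CHT025 and WFYT025 of the early season, and 18, 7 and 12 rose and 12, 13 and 14 fell in the middle season (19 rose in WFB adjusted over the list alone). Camera called the last of these lower (adjusted p = 0.00193, but adjusted p = 0.185 with an estimated correlation), although the list's median was 0.11.

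Nitrogen assimilation and remobilisation genes rose on day 10 in CHT025 in both seasons and in WFYT025 of the early season. Of 9 genes, 7 rose and 1 fell in CHT025 of the early season (camera adjusted p = 0.000942, and adjusted p = 0.024 with an estimated correlation). In its middle season 5 rose and 1 fell (0.00532, and adjusted p = 0.0321 with an estimated correlation). Another 7 rose and 1 fell in WFYT025 of the early season (0.00209, and adjusted p = 0.0165 with an estimated correlation). GS1;1, a cytosolic glutamine synthetase that re-assimilates ammonium for export, rose in all 6 comparisons, from 45 ± 2.4 to 180 ± 4.74 FPKM in CHT025 of the early season (log2 1.97). The nitrate reductase genes NIA1 and NIA2 rose most in WFB of the early season, NIA1 from 4.51 ± 0.181 to 77.4 ± 4.35 FPKM (log2 3.83) and NIA2 by 3.41. In WFB 5 members rose and 3 fell in the early season (0.0255, but adjusted p = 0.138 with an estimated correlation) and 3 rose and 5 fell in the middle season, without a call. In WFYT025 of the middle season 2 rose and 5 fell, also without a call.

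Starch genes changed in opposite directions in the 2 seasons. Of 14 starch synthesis and turnover genes, 10, 9 and 8 rose and 2, 2 and 4 fell in WFB, CHT025 and WFYT025 of the early season. Of the same genes 0, 0 and 2 rose and 8, 12 and 8 fell in the middle season (4 rose in WFYT025 adjusted over the list alone). Camera called all 6 (adjusted p = 0.00324, 0.00114, 0.0387, 0.00063, 8.03e-07 and 0.000484). With an estimated correlation the fall in CHT025 of the middle season was kept (adjusted p = 0.0287) and the others were not (adjusted p = 0.19, adjusted p = 0.2, adjusted p = 0.309, adjusted p = 0.183 and adjusted p = 0.169). SSI, a starch synthase, rose from 14.2 ± 0.9 to 95.9 ± 2.53 FPKM in WFB of the early season and fell from 122 ± 1.1 to 56.6 ± 1.49 in the middle season. GBSSII, which makes amylose in leaves, rose by 2.77 in the first and fell by 0.64 on the log2 scale in the second. Sucrose genes rose in the early season in CHT025 (9 of 13 up, 1 down; camera adjusted p = 0.00114, but adjusted p = 0.0508 with an estimated correlation) and WFYT025 (10 up, 0 down; 0.00279, but adjusted p = 0.0578 with an estimated correlation). SPS1, a sucrose-phosphate synthase, rose in the early season by 2.34, 2.04 and 2.29 in WFB, CHT025 and WFYT025. The phloem sucrose transporter gene SUT1 rose by 1.55 and 1.04 in CHT025 and WFYT025 and fell by 0.77 in WFB on the log2 scale. In WFB 5 members rose and 5 fell in the early season and 5 rose and 4 fell in the middle season (3 and 4 after quantile normalization). In the middle season 4 rose and 4 fell in CHT025 (5 fell adjusted over the list alone) and 3 rose and 6 fell in WFYT025 (7 fell adjusted over the list alone; camera adjusted p = 0.0424, but adjusted p = 0.185 with an estimated correlation).

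Of 9 genes of chlorophyll breakdown and senescence, 5, 4 and 7 rose and 3, 4 and 2 fell in WFB, CHT025 and WFYT025 of the early season, and 5, 6 and 6 rose and 1, 1 and 0 fell in the middle season. For CHT025 of the middle season camera called the list higher (2 fell adjusted over the list alone; adjusted p = 0.025, but adjusted p = 0.0722 with an estimated correlation). SGR, which starts chlorophyll breakdown by removing magnesium, rose by 1.96, 1.66 and 1.75 in the early season and by 0.92 and 0.91 in CHT025 and WFYT025 of the middle season, with 0.08 in WFB (adjusted p = 0.424). PAO, the next oxygenase of the pathway, rose by 0.20 to 0.73 in 5 comparisons. NYC1, a chlorophyll b reductase, fell in the early season by 1.35, 0.64 and 0.97 on the log2 scale.

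Of 18 clock and flowering time genes, 4, 3 and 4 rose and 10, 9 and 11 fell in the early season (5 rose in WFB adjusted over the list alone). For the middle season the numbers were 11, 4 and 8 rising and 4, 7 and 8 falling. Camera called the list lower in WFYT025 in both seasons (adjusted p = 0.0273 and 0.0424, but adjusted p = 0.27 and adjusted p = 0.276 with an estimated correlation). LHY, a MYB transcription factor of the clock that peaks at dawn, rose in the early season from 23.7 ± 0.353 to 385 ± 14.7 FPKM in WFB, from 123 ± 3.14 to 688 ± 45.5 in CHT025 and from 63.2 ± 0.411 to 623 ± 4.47 in WFYT025. GI and FKF1, which are high later in the day, fell in those comparisons, FKF1 from 34.3 ± 1.67 to 2.98 ± 0.185 FPKM in WFB. In the middle season LHY changed by -0.49, 0.04 (adjusted p = 0.437) and -1.12. The florigen gene Hd3a rose by 0.27 to 1.31 in all 6 comparisons.

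**Figure D2:**
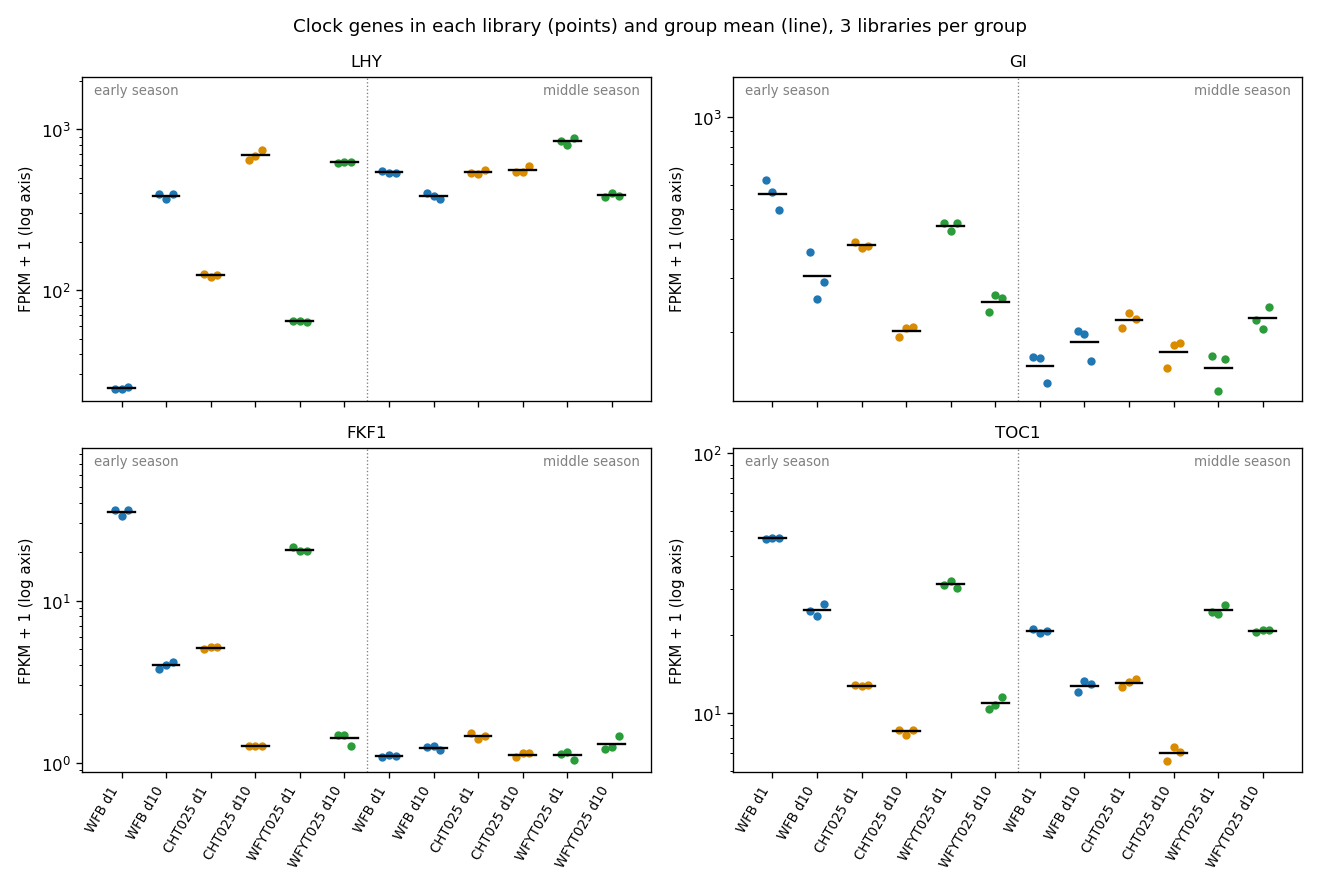
Points are single libraries and lines are means of 3 libraries for the clock genes LHY, GI, FKF1 and TOC1, with FPKM + 1 on a log axis and the 12 groups of variety and day on the horizontal axis, early season left and middle season right. In the early season LHY lies between 23.7 and 123 FPKM on day 1 and between 385 and 688 on day 10, while GI, FKF1 and TOC1 are higher on day 1.

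Heat shock and protein folding genes fell on day 10 in CHT025 of the middle season, where 85 of 167 fell and 22 rose (89 and 24 adjusted over the list alone; camera adjusted p = 1.44e-10, and adjusted p = 0.000941 with an estimated correlation). The disaggregase HSP101 fell from 47 ± 3.61 to 12.5 ± 0.764 FPKM (log2 -1.83), HSP90 (LOC_Os04g01740) from 9.57 ± 2.28 to 0.543 ± 0.0153, and small heat shock protein genes LOC_Os03g16020 and LOC_Os03g16030 fell by 3.84 and 3.58 on the log2 scale. The heat shock factor gene HSFA2A fell by 2.08 on that scale. In WFB, CHT025 and WFYT025 of the early season 44, 59 and 67 rose and 82, 58 and 54 fell, without a camera call. In WFB and WFYT025 of the middle season 74 and 87 rose and 42 and 30 fell (88 rose in the last adjusted over the list alone), also without a camera call. Quantile normalization turned the last split to 54 rising and 63 falling.

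Of 377 defence genes, 143 rose and 54 fell in CHT025 of the middle season, and 172 and 71 in WFYT025 of the early season (171 and 69 adjusted over the list alone). In WFYT025 of the middle season 206 rose and 51 fell (208 rose adjusted over the list alone). Camera called these (adjusted p = 0.00122, 0.0154 and 0.0424), and no call was kept with an estimated correlation (adjusted p = 0.0923, adjusted p = 0.245 and adjusted p = 0.276). In WFB 109 rose and 159 fell in the early season and 195 rose and 86 fell in the middle season (196 and 87 adjusted over the list alone), without a call. In CHT025 of the early season 96 rose and 119 fell (93 rose adjusted over the list alone), also without a call. Quantile normalization turned the 2 early splits to 136 rising and 114 falling and to 131 and 88, and gave 149 and 104 in WFYT025 of the middle season. Phenylalanine ammonia-lyase, the entry enzyme of phenylpropanoid synthesis, rose in WFB of the middle season from 1.35 ± 0.508 to 188 ± 32.2 FPKM (LOC_Os02g41630; log2 6.34), and the pathogenesis-related gene PBZ1 from 26.3 ± 4.16 to 272 ± 47.3. WRKY71 (LOC_Os02g08440) and the chitinase gene CHIT1 (LOC_Os02g39330) fell by 3.60 and 3.76 there and by 4.26 and 3.66 in CHT025 of the early season, on the log2 scale. In WFYT025 of the middle season a harpin-induced protein gene (LOC_Os01g64470) rose by 6.17 and an NB-ARC disease resistance gene (LOC_Os04g43440) by 5.80. Of 7 abscisic acid and dehydration genes, 0 rose and 6 fell in WFB of the middle season (camera adjusted p = 0.000112, but adjusted p = 0.0593 with an estimated correlation). In CHT025 of that season 1 rose and 5 fell (0.000627, and adjusted p = 0.039 with an estimated correlation). In WFB and WFYT025 of the early season 4 rose and 0 fell in each (0.0118 and 0.0347, but adjusted p = 0.176 and adjusted p = 0.245 with an estimated correlation). In CHT025 of the early season 1 rose and 5 fell and in WFYT025 of the middle season 5 rose and 1 fell, without a call. ABA8OX1, which breaks down abscisic acid, fell by 5.13 on the log2 scale in CHT025 of the early season and rose by 4.22 in WFYT025 of the middle season.

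Cell division genes fell in WFYT025 of the early season (41 of 60 down, 8 up; camera adjusted p = 3.85e-05, and adjusted p = 0.00353 with an estimated correlation), with a core histone gene (LOC_Os10g39410) at log2 -2.49. In WFB of the middle season 40 rose and 4 fell (41 rose adjusted over the list alone; 0.0187, but adjusted p = 0.159 with an estimated correlation). In the remaining comparisons 18 rose and 29 fell (WFB, early), 22 and 18 (CHT025, early), 8 and 11 (CHT025, middle) and 32 and 5 (WFYT025, middle), without a call. Adjusted over the list alone, 23 rose in CHT025 of the early season and 10 fell in its middle season. Of 34 proteasome genes, 2, 11 and 13 rose and 21, 6 and 7 fell in the early season, without a camera call. Across the middle season 17, 3 and 26 rose and 4, 6 and 0 fell (2 rose in CHT025 adjusted over the list alone), also without a call; after quantile normalization the 26 and 0 became 3 and 4. Of 8 antioxidant enzyme genes, 4, 4 and 5 rose and 4, 2 and 3 fell in the early season and 5, 3 and 5 rose and 1, 2 and 1 fell in the middle season, without a call. CATA, a catalase gene, is described with the season differences.

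**Figure D3:**
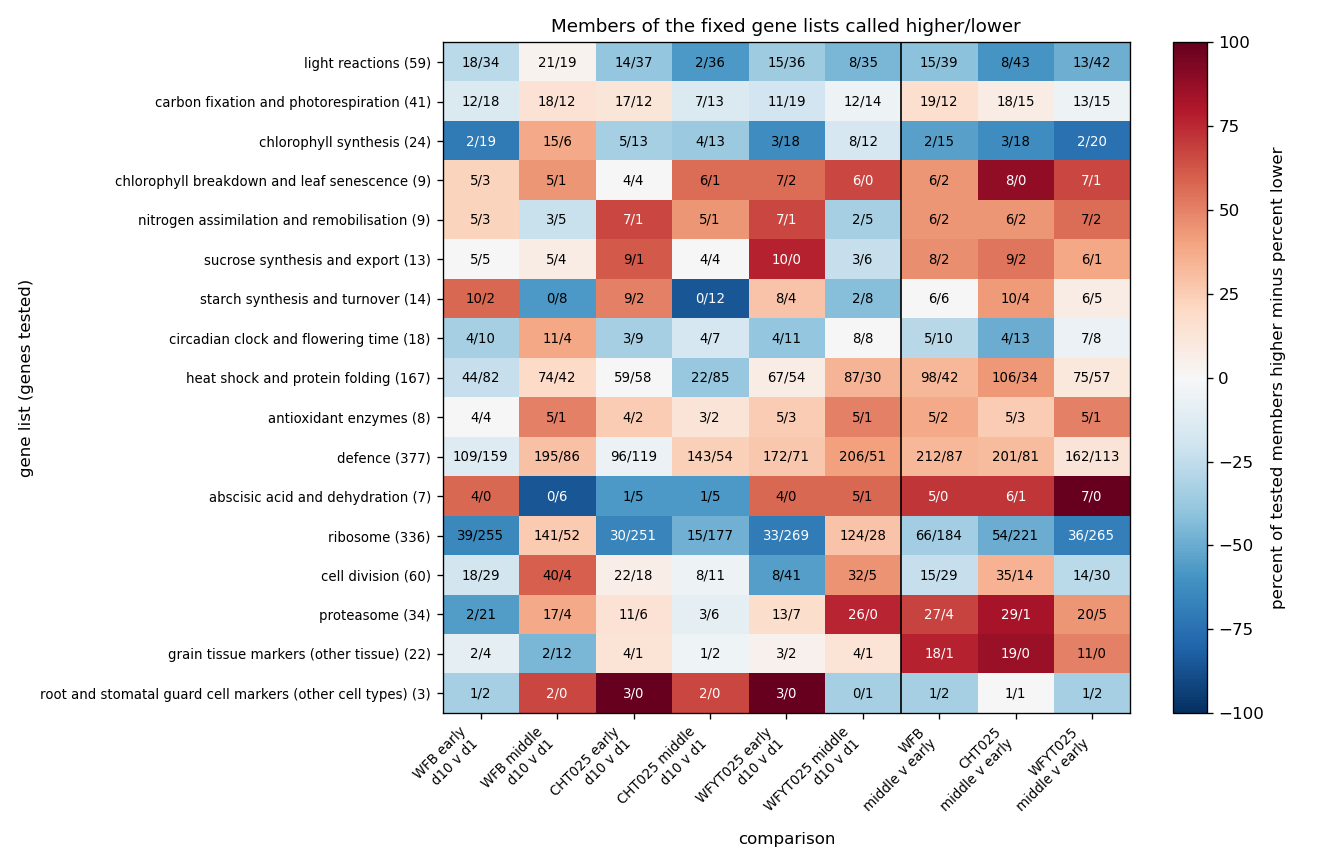
Each cell gives the members of a gene list (rows, with the number tested) called higher/lower by limma in a comparison (columns), and its colour gives the percent of tested members higher minus the percent lower. Ribosome genes fell on day 10 in the early season (269 of 336 in WFYT025), and chlorophyll synthesis genes were lower in the middle than in the early season (20 of 24 in WFYT025).

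Of 22 grain tissue marker genes, chosen to detect RNA of another tissue, 2, 4 and 3 rose and 4, 1 and 2 fell with day in the early season (3 rose in CHT025 and 2 in WFYT025 adjusted over the list alone). Between the days of the middle season 2, 1 and 4 rose and 12, 2 and 1 fell, and after quantile normalization 2 rose and 4 fell in WFYT025, where 2 rose adjusted over the list alone. Camera called the fall in WFB of the middle season (14 fell adjusted over the list alone; adjusted p = 0.0415, but adjusted p = 0.722 with an estimated correlation). GluA1, a glutelin of the rice endosperm, was at 90.1 ± 18.4 FPKM in WFB on day 1 of the middle season and at 5.66 ± 7.96 on day 1 of the early season. Its SD was close to or above its mean in many groups because replicate libraries differed. In 8 of the 12 groups some libraries lay at 1.7 FPKM or less and others at 11.9 or more. No day comparison called it (adjusted p = 0.6, 0.0626, 1, 0.807, 0.911 and 0.268). Of the 3 root and guard cell markers, LSI1, FAMA and SLAC1, 1, 3 and 3 rose and 2, 0 and 0 fell in the early season, and 2, 2 and 0 rose and 0, 0 and 1 fell in the middle season.

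**Figure D4:**
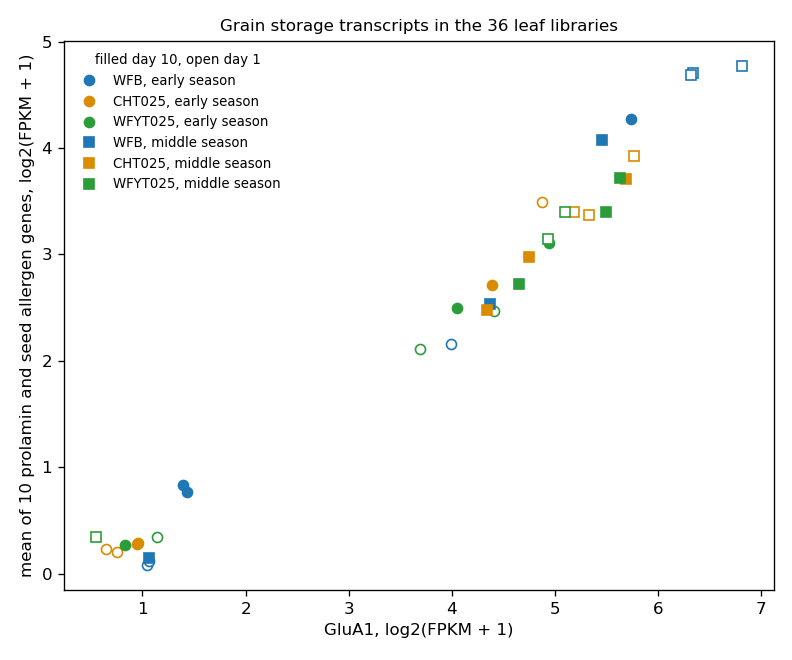
Each point is 1 of the 36 libraries, with GluA1 on the horizontal and the mean of 10 prolamin and seed allergen genes on the vertical axis, both as log2(FPKM + 1). Of the 36 libraries, 24 lie at 11.9 to 111 FPKM of GluA1 and 12 at 0.46 to 1.7, and replicates of 8 of the 12 groups lie in both clusters.

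The change from day 1 to day 10 differed between the seasons. A different time of day or light at harvest may be part of this difference, as weighed below. In WFB, 267 genes rose at least 2-fold in the early season and fell at least 2-fold in the middle season, and 261 did the opposite, while 61 rose and 30 fell in both. Independent lists of these sizes would share 59.1, 99.8, 68.1 and 86.7. In CHT025 33 rose in both, 60 fell in both, and 32 and 54 went opposite ways (10.3, 26.3, 13.7 and 19.9 for independent lists). In WFYT025 271 rose in both and 16 fell in both, with 61 and 152 opposite (88.4, 18.9, 18.3 and 91.2). The comparisons of 2 seasons share no library. A test of the difference called 9936 genes with a more positive and 4437 with a more negative change in the middle season in WFB, 6713 and 3908 in CHT025, and 8818 and 4192 in WFYT025. At least 2-fold they were 4005 and 2134, 1481 and 1035, and 3042 and 1375. After quantile normalization the splits were 7298 and 6006, 4975 and 5108, and 6010 and 6552 (2630 and 2680, 1178 and 1203, and 1983 and 2085 at least 2-fold).

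Named genes with the largest such differences in all 3 varieties were the catalase gene CATA, a universal stress protein gene (LOC_Os05g28740), a FAD-dependent oxidoreductase gene (LOC_Os07g34570), a plastid glutamate synthase gene (LOC_Os05g48200) and a light-induced protein gene (LOC_Os01g01340). CATA fell in WFB of the early season from 183 ± 13.2 to 7.92 ± 1.15 FPKM and rose in the middle season from 5.19 ± 1.2 to 191 ± 58 (difference 9.30 ± 0.37, adjusted p = 9.24e-20). The differences in CHT025 and WFYT025 were 4.25 and 6.21. The universal stress protein gene differed by 9.56, 5.41 and 5.10, and the glutamate synthase gene by 8.47, 2.90 and 4.02. The oxidoreductase gene differed by 5.07, 4.13 and 7.91 and the light-induced protein gene by 5.40, 4.12 and 4.92. More negative in the middle season were WRKY76 (LOC_Os09g25060; -7.33, -1.79 and -4.89), early light-induced protein genes LOC_Os07g08150 (-6.05, -3.27 and -4.61) and LOC_Os07g08160 (-7.70, -1.74 and -4.15). So were a chalcone synthase gene (LOC_Os11g32650; -3.87, -6.06 and -3.83) and a late embryogenesis abundant gene (LOC_Os01g21250; -7.92, -2.18 and -3.40). Of the lists, starch and ribosome were called in all 3 varieties. For starch, 10 of 14 genes in WFB, 11 in CHT025 and 9 in WFYT025 changed more negatively in the middle season and 2, 1 and 4 more positively (2 in CHT025 adjusted over the list alone), with camera adjusted p = 0.000246, 7.8e-07 and 0.00109. With an estimated correlation these were adjusted p = 0.139, adjusted p = 0.0249 and adjusted p = 0.145. Of the 22 grain tissue markers 12, 4 and 3 changed more negatively and 5, 0 and 3 more positively (13 in WFB and 2 in CHT025 more negatively adjusted over the list alone), with medians of -1.92, -0.66 and 1.06 and no camera call (0.149, 0.066 and 0.97). Ribosome genes changed more positively in the middle season in 250, 170 and 269 of 336 cases and more negatively in 50, 33 and 29 (270 and 30 in WFYT025 adjusted over the list alone; 0.00478, 0.0191 and 1.51e-07). None of these calls was kept with an estimated correlation (adjusted p = 0.382, adjusted p = 0.432 and adjusted p = 0.0606).

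Across both days, more chlorophyll synthesis and ribosome genes were lower than higher in flag leaves of the middle season against the early season, and more proteasome genes were higher than lower. The ribosome call was not kept in WFB with an estimated correlation (adjusted p = 0.236), nor the proteasome call in WFB (adjusted p = 0.0526) and WFYT025 (adjusted p = 0.141). PORA was at 691 ± 54.1, 283 ± 24.5 and 329 ± 23.9 FPKM on day 1 of the early season in WFB, CHT025 and WFYT025. On day 1 of the middle season it was at 7.06 ± 1.14, 21.6 ± 2.22 and 5.99 ± 0.479 (season log2 -4.42, -2.94 and -4.44, each ± 0.08; adjusted p = 3.43e-29, 3.09e-24 and 5.15e-29). The FAD-dependent oxidoreductase gene LOC_Os07g34570 was at 5234 ± 223 and 2.32 ± 0.929 FPKM on day 1 of the early and middle season in WFB (season log2 -8.13 ± 0.09). Ferritin-1, the plastid iron store, is encoded by near-identical copies on which reads may be split, LOC_Os12g01530 and LOC_Os11g01530. The first was at 28.6 ± 0.31 and 1736 ± 42.3 FPKM on day 1 of the early and middle season in CHT025 (season log2 2.72, 5.26 and 4.98 in WFB, CHT025 and WFYT025).

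Further named genes higher in the middle season in all 3 varieties were a cysteine protease gene (LOC_Os03g54130; log2 3.86, 5.21 and 5.63 in WFB, CHT025 and WFYT025), an integral membrane protein gene (LOC_Os09g23300; 2.94, 5.47 and 5.24) and a peptidyl-prolyl isomerase gene (LOC_Os04g28420; 3.38, 5.93 and 4.19). So were the early light-induced gene LOC_Os07g08150 (5.08, 2.85 and 5.26), a glycosyl hydrolase gene (LOC_Os02g01590; 4.90, 4.53 and 3.37) and a MATE efflux gene (LOC_Os03g08900; 4.42, 3.70 and 3.73). Lower were an AP2 transcription factor gene (LOC_Os09g11480; -4.77, -2.27 and -4.14), the universal stress protein gene LOC_Os05g28740 (-3.72, -2.27 and -4.69) and the light-induced protein gene LOC_Os01g01340 (-3.80, -2.29 and -4.35). Also lower were a transketolase gene (LOC_Os05g33840; -3.23, -2.75 and -3.54), a zinc finger gene (LOC_Os08g03310; -2.57, -2.57 and -4.07) and a HAD phosphatase gene (LOC_Os01g09540; -4.17, -1.72 and -3.26). Limma called 7906 genes higher and 6442 lower in the middle season in WFB (1672 and 853 at least 2-fold), 9115 and 4886 in CHT025 (1061 and 438) and 6762 and 7326 in WFYT025 (1266 and 978). Quantile normalization gave 6587 higher and 7919 lower in WFB (1409 and 1048 at least 2-fold) and 6497 and 6998 in CHT025 (799 and 642), so the balance among all called genes there depends on the scaling. In all 3 varieties 440 genes were at least 2-fold higher and 205 at least 2-fold lower, against 6.5 and 1.06 for independent lists.

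Of the 24 chlorophyll synthesis genes, 15, 18 and 20 were lower and 2, 3 and 2 higher in the middle season in WFB, CHT025 and WFYT025 (camera adjusted p = 0.000225, 1.33e-08 and 9.22e-07). With an estimated correlation all were kept (adjusted p = 0.00765, adjusted p = 0.000168 and adjusted p = 0.000794). PORB was lower by log2 -1.46, -1.02 and -1.45. Ribosome genes were lower in 184, 221 and 265 cases and higher in 66, 54 and 36 (222 and 55 in CHT025 adjusted over the list alone; camera adjusted p = 0.00107, 3.2e-15 and 1.69e-14; adjusted p = 0.236, adjusted p = 0.0068 and adjusted p = 0.01 with an estimated correlation). Light reaction genes were lower in 39, 43 and 42 cases and higher in 15, 8 and 13 (40 and 16 in WFB adjusted over the list alone; 0.000232, 3.06e-11 and 0.000114, none kept at adjusted p = 0.239, adjusted p = 0.0664 and adjusted p = 0.286 with an estimated correlation). CAB2R, a light-harvesting protein gene, was at 13941 ± 518 FPKM on day 1 of the early season and 2896 ± 110 on day 1 of the middle season in WFB, and RBCS2 was lower by log2 -0.96, -1.64 and -0.99.

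Proteasome genes were higher in 27, 29 and 20 of 34 cases and lower in 4, 1 and 5 (camera adjusted p = 0.00477, 0.000285 and 0.0474; adjusted p = 0.0526, adjusted p = 0.0068 and adjusted p = 0.141 with an estimated correlation). Chlorophyll breakdown and senescence genes were higher in 6, 8 and 7 of 9 cases (0.0776, 0.00149 and 0.0112; adjusted p = 0.0135 in CHT025 and adjusted p = 0.0549 in WFYT025 with an estimated correlation). SGR was higher by log2 2.68, 3.22 and 3.37 and OsNAP by 1.01, 1.38 and 0.74. Heat shock genes were higher in 98, 106 and 75 of 167 cases and lower in 42, 34 and 57 (adjusted over the list alone 108 and 36 in CHT025 and 76 higher in WFYT025; 0.0053, 0.006 and 0.185; adjusted p = 0.146 and adjusted p = 0.113 in WFB and CHT025 with an estimated correlation). HSP101 stood at log2 1.37, 2.44 and 1.33. Defence genes were higher in 212, 201 and 162 cases and lower in 87, 81 and 113 (214 higher in WFB adjusted over the list alone; 0.0221, 0.298 and 0.0911; adjusted p = 0.239 in WFB with an estimated correlation), with WRKY45, a regulator of induced resistance, at 2.39, 2.14 and 3.56. Abscisic acid and dehydration genes were higher in 5, 6 and 7 of 7 cases (0.0482, 0.0713 and 0.000803; adjusted p = 0.239 in WFB and adjusted p = 0.0549 in WFYT025 with an estimated correlation). Clock and flowering time genes were lower in 10 and 13 of 18 cases and higher in 5 and 4 in WFB and CHT025 (0.0444 and 0.0036, but adjusted p = 0.266 and adjusted p = 0.152 with an estimated correlation), while 8 were lower and 7 higher in WFYT025 without a call (0.398). Cell division genes were lower in 29 of 60 cases and higher in 15 in WFB (0.0053, but adjusted p = 0.0759 with an estimated correlation). In CHT025 35 cell division genes were higher and 14 lower (0.0894, and 0.0338 after quantile normalization), and in WFYT025 14 were higher and 30 lower (0.215). In WFYT025 nitrogen genes were higher in 7 of 9 cases (0.0296, but adjusted p = 0.0852 with an estimated correlation) and antioxidant enzyme genes in 5 of 8 (0.046, but adjusted p = 0.281 with an estimated correlation). Beside these, the grain tissue markers were higher in 18, 19 and 11 of 22 cases (10 in WFYT025 adjusted over the list alone; 0.0766, 0.0365 and 0.046; adjusted p = 0.531 in CHT025 and adjusted p = 0.544 in WFYT025 with an estimated correlation). GluA1 was higher in WFB (log2 2.62 ± 0.95, adjusted p = 0.0144) and CHT025 (3.08 ± 0.95, adjusted p = 0.00478), with 1.21 in WFYT025 (adjusted p = 0.249). Of the 18 libraries of each season, 16 of the middle and 8 of the early season lay in the cluster with 11.9 FPKM or more of GluA1.

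In the hybrid, 99 genes were at least 2-fold below both parents on day 1 of the early season and at least 2-fold above both on day 10 of the middle season. An NB-ARC disease resistance gene (LOC_Os04g43440) was at 109 ± 4.41 FPKM in WFYT025 on day 10 of the middle season, against 2.15 ± 0.606 in WFB and 4.46 ± 0.457 in CHT025 (log2 5.15 ± 0.28 and 4.34 ± 0.28, adjusted p = 4.72e-16 and 3.65e-14). A glycerol-3-phosphate dehydrogenase gene (LOC_Os05g41590) was at 81.9 ± 1.33 FPKM against 4.12 ± 0.214 and 3.13 ± 0.635, and an ethylene-responsive factor gene (LOC_Os03g09170) at 43.8 ± 0.943 against 1.92 ± 0.544 and 1.78 ± 0.316. On day 1 of the early season an EF hand gene (LOC_Os06g46950) was at 2.35 ± 0.3 FPKM in the hybrid against 64.8 ± 7.83 in WFB and 91.8 ± 2.71 in CHT025. A DREB transcription factor gene (LOC_Os09g35010) was at 0.26 ± 0.183 against 16.5 ± 0.967 and 40.2 ± 3.2, and an AP2 gene (LOC_Os04g52090) at 1.2 ± 0.0862 against 25.2 ± 1.75 and 55.5 ± 2.71. On day 10 of the middle season these same 3 genes were above both parents, by log2 1.51 and 3.10, 2.24 and 5.26, and 1.12 and 2.23.

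**Figure D5:**
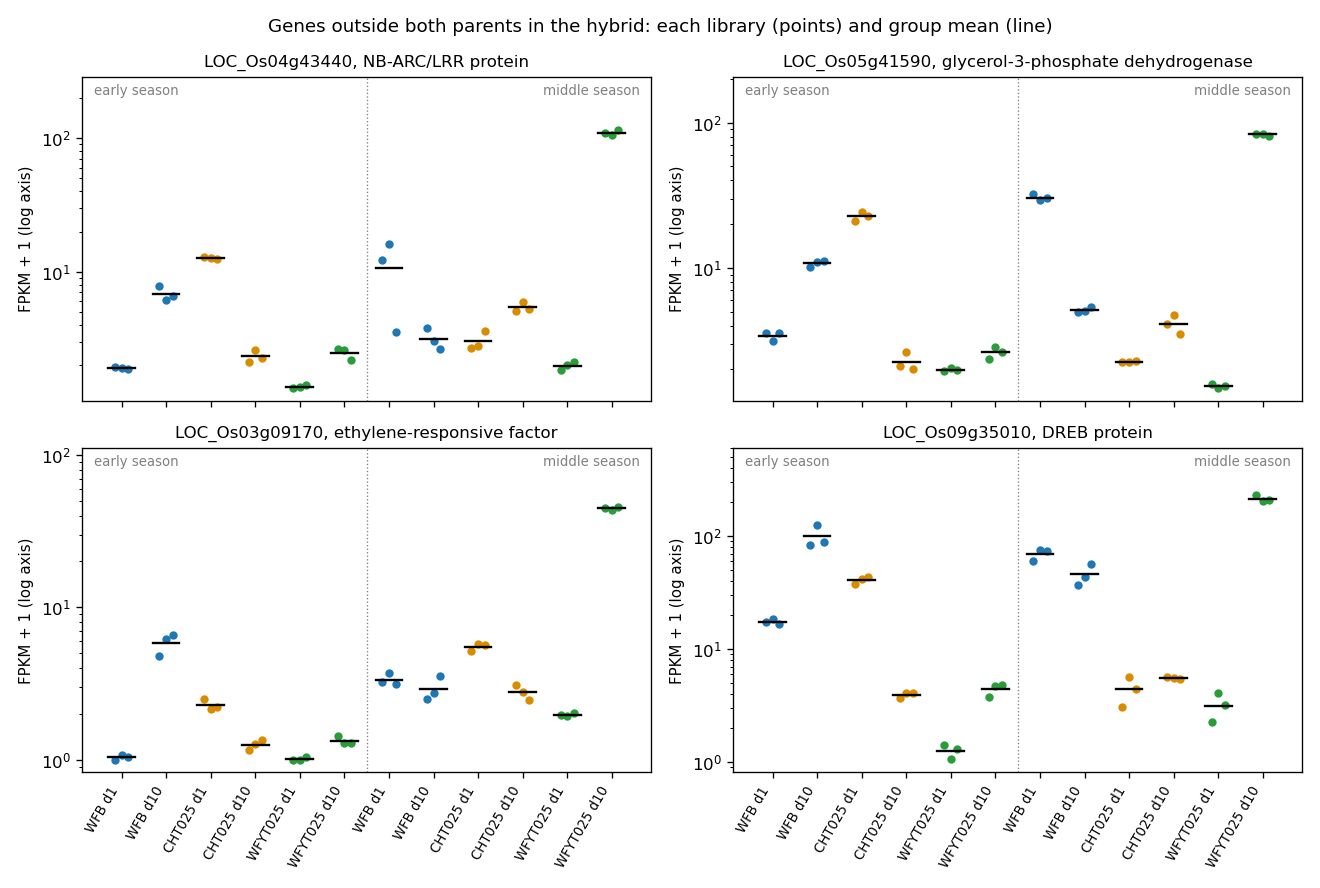
Points are single libraries and lines are means of 3 libraries for LOC_Os04g43440, LOC_Os05g41590, LOC_Os03g09170 and LOC_Os09g35010, with FPKM + 1 on a log axis and the 12 groups of variety and day on the horizontal axis, early season left and middle season right. On day 10 of the middle season the hybrid reaches 109, 81.9, 43.8 and 213 FPKM, and in each panel its 3 libraries lie above those of both parents.

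At least 2-fold outside both parents were 24 genes above and 150 below on day 1 of the early season, and 26 and 161 on day 1 of the middle season. On day 10 there were 41 and 9 in the early season and 471 and 65 in the middle season. Counting all called genes there were 756 above and 1516 below, 1060 and 4377, 1212 and 645, and 2013 and 2943. Independent calls against each parent would give 650.4 and 1292.6, 629.1 and 3981.8, 1209 and 716.4, and 916.6 and 2092. Part of any excess may come from the hybrid libraries that both comparisons share. In 20 simulations the hybrid and both parents were given equal means, and 0 genes fell outside both. These simulations cannot show how many genes would do so where the parents differ. After quantile normalization the splits of the first 3 were 1195 and 1080, 2657 and 1847, and 1010 and 899, so the surplus of lower genes among all called genes on day 1 depends on the scaling. At least 2-fold, quantile normalization gave 26 above and 132 below on day 1 of the early season, and 63 and 74 on day 1 of the middle season. Against WFB limma called 3966 higher and 4983 lower, 4720 and 6589, 6709 and 4274, and 4684 and 5604, and against CHT025 3048 and 4821, 2477 and 11231, 3349 and 3115, and 3637 and 6938 in the same order of settings. At least 2-fold there were 438 and 530, 520 and 1310, 886 and 477, and 932 and 605 against WFB, and 331 and 730, 294 and 1048, 395 and 95, and 845 and 358 against CHT025. Quantile normalization gave 6906 and 4907 on day 1 of the middle season (706 and 1086 at least 2-fold) and 5530 and 5622 on day 10 of the early season against WFB. Against CHT025 it gave 4771 and 3648 on day 1 of the early season and 5183 and 5361 on day 1 of the middle season (538 and 474 at least 2-fold).

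Against the mid-parent, 3061 genes were higher and 4328 lower on day 1 of the early season (142 and 421 at least 2-fold), 2714 and 9275 on day 1 of the middle season (136 and 787). On day 10 there were 4944 and 2753 in the early season (210 and 76) and 3841 and 6326 in the middle season (677 and 236). Quantile normalization gave 4157 and 3146, 5930 and 4850, and 4071 and 3893 for the first 3, and 261 and 481 at least 2-fold on day 1 of the middle season. In each setting 2406, 3288, 2761 and 1919 genes differed from both parents and lay between them. The median distance of the hybrid was 0.2, 0.28, 0.26 and 0.24 on the log2 scale from WFB and 0.17, 0.38, 0.15 and 0.24 from CHT025. Of the genes above the mid-parent in all 4 settings, most named ones were expressed in WFB and close to 0 in CHT025. An NBS-LRR gene (LOC_Os06g17970) was at 28.2 ± 1.55 FPKM in the hybrid, 22.1 ± 0.919 in WFB and 0.0167 ± 0.00577 in CHT025 on day 1 of the early season, and stood at 2.59, 2.12, 1.95 and 1.91 against the mid-parent. A short-chain dehydrogenase gene (LOC_Os02g42810; 2.68, 1.96, 1.81 and 1.81), a cytochrome P450 gene (LOC_Os08g39640; 2.62, 1.82, 1.96 and 1.49), a hypersensitive-induced reaction protein gene (LOC_Os06g04399; 1.22 to 2.01) and a DUF26 kinase gene (LOC_Os07g43570; 2.94, 0.36, 1.37 and 1.23) had the same pattern of levels. For such genes the mean of logs lies far below the mean of levels: against the arithmetic mid-parent the NBS-LRR gene was at 1.27, 0.11, -0.02 and -0.12 and the kinase gene at -0.11, -0.66, -1.17 and -0.60.

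A plastid ribosomal protein L33 gene (LOC_Os08g15312) was above both parents in all 4 settings, at 12.8 ± 1.77 FPKM against 1.34 ± 0.12 and 0.303 ± 0.188 on day 1 of the early season. A near-identical copy (LOC_Os10g21308) was below both, by log2 -2.63 and -2.68 on day 10 of the early season. Reads can be split between such copies, so both values are uncertain. Lower than the mid-parent in all 4 settings were a plant-specific TIGR01589 domain gene (LOC_Os03g17200; -0.91, -0.87, -0.56 and -2.08), a P450 gene (LOC_Os12g05440; -0.77, -2.11, -0.61 and -0.53) and a serine carboxypeptidase gene (LOC_Os11g24510; -0.20, -1.51, -0.75 and -1.54). So were a MATE efflux gene (LOC_Os04g30490; -1.98, -1.17, -0.64 and -0.20) and a HORMA domain gene (LOC_Os01g07170; -0.30, -0.94, -0.92 and -1.11). Farthest above both parents on day 1 were also a trehalose phosphatase gene (LOC_Os05g03810; 1.84 and 1.71 against WFB and CHT025) and a histone H1 gene (LOC_Os04g18090; 1.89 and 1.64) in the early season. A P450 gene (LOC_Os09g10340; 2.02 and 3.67) and a MYB gene (LOC_Os01g47370; 1.55 and 1.59) were so in the middle season. Farthest below both on day 1 of the middle season were transporter genes LOC_Os07g33910 (-3.74 and -3.47), LOC_Os07g33954 (-3.46 and -3.32) and LOC_Os07g34006 (-3.54 and -3.31), which are similar copies. On day 10 of the early season an isoflavone reductase gene (LOC_Os01g01660; 2.91 and 2.79) and a plastocyanin-like gene (LOC_Os12g26880; 2.27 and 1.88) were above both, and a ubiquitin gene (LOC_Os06g46770; -2.81 and -1.75) and a core histone gene (LOC_Os09g38020; -1.36 and -1.37) below both. On day 10 of the middle season a glycosyl hydrolase gene (LOC_Os02g01590; -3.02 and -2.46), a MYB gene (LOC_Os11g47460; -2.07 and -2.64) and RIPER2 (LOC_Os04g29550; -2.02 and -2.03) were below both.

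Among the lists, chlorophyll synthesis genes were above the mid-parent on day 1 of the early season (15 of 24 higher, 2 lower; 17 and 3 adjusted over the list alone; camera adjusted p = 0.000106, and adjusted p = 0.00457 with an estimated correlation). CAO1, which makes chlorophyll b, stood at log2 0.51. Cell division genes were above it in that setting (25 of 60 higher, 2 lower; 6.93e-06, and adjusted p = 0.00373 with an estimated correlation). They were below it on day 10 of the early season (21 lower, 8 higher; 22 lower adjusted over the list alone; 8.15e-05, and adjusted p = 0.0149 with an estimated correlation). The core histone gene LOC_Os10g39410 stood at 1.66 in the first and -1.49 in the second. On day 1 of the middle season nitrogen assimilation genes were above the mid-parent (7 of 9 higher, 1 lower; 2.17e-05, and adjusted p = 0.00407 with an estimated correlation), with NIA1 at 0.91 and GS1;1 at 0.57. Heat shock genes were below it there (126 of 167 lower, 17 higher; 128 lower adjusted over the list alone; 1.12e-06, and adjusted p = 0.00785 with an estimated correlation). HSP24.1, a mitochondrial small heat shock protein gene, was at 17.3 ± 0.295 FPKM in the hybrid against 79.4 ± 7.84 in WFB and 163 ± 8.95 in CHT025. Proteasome genes were also below it (32 of 34 lower, 0 higher; 0.00186, and adjusted p = 0.0226 with an estimated correlation), but after quantile normalization 13 were lower and the adjusted p was 0.0894. Ribosome genes were below it (261 lower, 19 higher; 264 lower adjusted over the list alone; 7.27e-08, but adjusted p = 0.0534 with an estimated correlation). Of the grain tissue markers 14 of 22 were also lower there and 1 higher, with a median of -1.24 and no camera call (0.686). On day 10 of the middle season abscisic acid and dehydration genes were above it (6 of 7 higher, 0 lower; 2.65e-05, and adjusted p = 0.0451 with an estimated correlation), with ABA8OX1 at 3.24 and NCED4, an enzyme of abscisic acid synthesis, at 1.04.

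Other camera calls against the mid-parent were not kept with an estimated correlation. Ribosome genes were above it on day 1 of the early season (117 higher, 17 lower; 6.53e-05, but adjusted p = 0.284 with an estimated correlation). They were below it on day 10 of the early season (74 lower, 35 higher; 70 lower adjusted over the list alone; 0.00145, but adjusted p = 0.47 with an estimated correlation) and of the middle season (187 lower, 43 higher; 193 and 44; 2.6e-05, but adjusted p = 0.242 with an estimated correlation). Light reaction genes were above it on day 1 of the early season (20 higher, 5 lower; 21 higher adjusted over the list alone; 0.00549, but adjusted p = 0.531 with an estimated correlation) and below it on day 10 (23 lower, 3 higher; 24 lower; 2.91e-05, but adjusted p = 0.47 with an estimated correlation). On day 1 of the middle season camera called them higher (21 higher, 18 lower; 0.00304, but adjusted p = 0.458 with an estimated correlation), and quantile normalization turned this to 17 and 21. Carbon fixation genes were called higher on day 1 of the early season (15 higher, 7 lower; 0.0478, but adjusted p = 0.412 with an estimated correlation). On day 1 of the middle season they were called higher too (15 higher, 21 lower; 0.00869, but adjusted p = 0.303 with an estimated correlation), although their median was -0.15. Quantile normalization turned this to 13 higher and 8 lower, without a call (adjusted p = 0.733). Clock and flowering time genes were called higher on day 1 of the middle season (8 higher, 4 lower; 0.00186, but adjusted p = 0.152 with an estimated correlation) and lower on day 10 of the early season (13 lower, 3 higher; 4 higher adjusted over the list alone; 0.000743, but adjusted p = 0.251 with an estimated correlation). Defence genes were called higher in the latter setting (147 higher, 37 lower; 148 and 39 adjusted over the list alone; 0.0464, but adjusted p = 0.518 with an estimated correlation).

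Of 9 chlorophyll breakdown and senescence genes 4, 6, 1 and 5 were below and 0, 1, 1 and 2 above the mid-parent in the 4 settings, without a camera call (0.108, 0.545, 0.659 and 0.478). OsNAP stood at -0.50 on day 1 and -0.57 on day 10 of the middle season, with -0.04 and -0.13 in the early season (adjusted p = 0.678 and 0.128). SGR was higher on day 10 of the middle season (0.50) and was not called elsewhere, and SUT1 was lower on day 1 of the early season (-0.60) and day 10 of the middle season (-1.05). Hd3a was called lower in the early season (-0.44 and -0.26 on day 1 and day 10) and higher on day 1 of the middle season (0.22). GluA1 was not called against the mid-parent (adjusted p = 0.529, 0.0692, 0.626 and 0.499).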

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

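Each result in this part stands here because the change from day 1 to day 10 differed between the seasons by a test of the difference itself. The tests of the clock genes and of the scaling were chosen after the result was seen, as were all comparisons with other splits of the libraries; the test for swapped days was written before.

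The difference was called for 14373 genes in WFB, 10621 in CHT025 and 13010 in WFYT025. In WFB 1 of 100 splits of the libraries, the real one, gave as many genes (highest other 11561). So did 1 of 100 in WFYT025 (highest other 11078). In CHT025 5 of 100 did, up to 14001. The split with 14001 exchanges the seasons of 1 day, which makes it the season test, and the highest without it was 10959. That split was not drawn in WFB and WFYT025. There it would give the season counts, 14348 and 14088, the second above the real 13010. These shares depend on the draw and replicates may be technical, so chance is not settled.

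In WFB the early, the middle and the difference values were -2.97, 1.05 and 4.01 for PORA (adjusted p = 2.32e-20), -1.71, 1.34 and 3.04 for SUS2, a sucrose synthase (2.66e-24), and 2.68, -1.09 and -3.77 for the starch synthase SSI (1.67e-29). The catalase genes CATA and CATB had -4.37, 4.93 and 9.30 (9.24e-20) and -1.09, 1.56 and 2.66 (2.82e-20). The pathogenesis-related genes PBZ1 and PR10b had -1.58, 3.32 and 4.89 (2.14e-15) and -1.06, 2.94 and 4.0 (4.52e-13). NCED5, of abscisic acid synthesis, had 2.13, -1.29 and -3.43 (2.15e-21), and ABA8OX1, of its breakdown, 1.78, -2.94 and -4.72 (4.74e-21). In CHT025 HSP24.1 had 1.20, -2.33 and -3.53 (1.48e-18) and CATA -2.67, 1.58 and 4.25 (3.83e-11). In WFYT025 the sucrose exporter gene SWEET13 had 1.38, -1.23 and -2.61 (7.87e-12), AGPL1, of starch synthesis, 1.06, -1.25 and -2.31 (1.34e-14), SSI 1.88, -1.10 and -2.98 (2.65e-26), the clock gene LHY 3.28, -1.12 and -4.40 (7.74e-30), and CATA -2.53, 3.69 and 6.21 (3.22e-15).

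In CHT025 the lists of nitrogen assimilation (median difference -0.5, 1 gene more positive and 7 more negative), sucrose (-0.66, 1 and 9), starch (-0.73, 1 and 11) and heat shock (-0.1, 41 and 75) changed more negatively in the middle season. Adjusted over the list alone, 2 sucrose and 2 starch genes were more positive, and 43 and 76 heat shock genes were called. With an estimated correlation each was kept at adjusted p = 0.0249; after quantile normalization the nitrogen list had an adjusted p of 0.0711. In WFYT025 the nitrogen list had a median difference of -0.63 (1 and 7; camera adjusted p = 0.000524, and adjusted p = 0.0173 with an estimated correlation) and the cell division list 0.71 (43 and 4, or 43 and 5 adjusted over the list alone; 0.00159, and adjusted p = 0.0479 with an estimated correlation).

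The opposite changes in the 2 seasons were weighed as 1 pattern. At 2-fold they outnumbered shared changes in WFB only, where labels and scaling were tested. Swapped days in the labels of WFB of the middle season are argued against: of the genes changed 2-fold in 1 direction in both seasons of CHT025 and called in that comparison of WFB, 88.5% (69 of 78) went in the same direction there. Time of day or light at harvest may have differed between the early-season days. LHY was lower and GI, PRR95, PRR59, TOC1 and FKF1 were higher on day 1 in 18 of 18 combinations of gene and variety, against 6 of 18 in the middle season. The authors' scaling stays open in part, since 78% (412 of 528) of the genes of WFB with opposite 2-fold changes kept them after quantile normalization. A difference between the crops themselves, in weather or in the course of grain filling, stays open and was not tested.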

How the results depend on the processing

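Of the 28 counts of called genes, all stayed within 1.5 times of the reported value with a pseudocount of 0.1, without the filter, with quantile normalization, with a replicate block, with the libraries of the comparison alone and with the level of grain storage transcripts as a covariate. So did the counts from the arithmetic mid-parent and from single days of the season comparison. The covariate and the single days were chosen after seeing the data. Leaving out 1 library at a time gave 80.8% to 99.3% of the reported count. Labels give no pairing: same-numbered libraries correlated at -0.32 to 0.35 after removal of group means, 0 of 14 comparisons had all such correlations over 0.1, and 4 of 18 day 1 libraries correlated best with their own number. With a replicate block, day 10 versus day 1, WFB, early season had 13187 called genes instead of 13216. Methods for counts were not run, since the files hold FPKM, and the depth of the libraries is unknown.

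Of 384 list tests 137 were called, and 38 were called with an estimated correlation, which widens the test by the correlation among list members; 99 were kept with quantile normalization and 137 with a replicate block. Of 426 values of 80 named genes, quantile normalization left 388 on their side of the threshold, moved 21 below and 9 above it, and turned 8. The turned values, for which the cause was not tested, were for day 10 against day 1 RBCS2 in the early season of WFB (0.28) and WFYT025 (0.33), and NYC1 (-0.18) and CAB1R (0.42) in the middle season of WFYT025. Against the mid-parent it was RBCS2 on day 10 of the early season (0.31), and for the season CAB1R in CHT025 (0.30) and WFYT025 (0.02). For the season difference of the day change in WFYT025 it was Hd3a (-0.32). With a pseudocount of 0.1, 423 values stayed on their side, 2 fell below and 1 rose above.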

Other observations

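Genes annotated as responding to chitin, a fungal cell wall component, moved together in several comparisons. Of 69 such genes 42 rose on day 10 in WFB of the early season (Fisher's exact test, adjusted p = 4.09e-07) and 49 in WFYT025 (4.75e-07), while 41 fell in WFB of the middle season (7.34e-09). In the hybrid 45 were below the mid-parent on day 1 of the early season (4.39e-10) and 46 above it on day 10 of the middle season (3.56e-13). Genes of the chloroplast thylakoid membrane went the other way on day 1 of the early season, with 131 of 259 above the mid-parent (2.66e-35), and on day 10 of the early season 98 were below it (2.61e-17). The plastid NAD(P)H dehydrogenase complex, which cycles electrons around photosystem I, had 10 of 10 genes below it there (2.59e-06).

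In the middle season, endoplasmic reticulum genes were higher than in the early season in WFB (236 of 381; Fisher's exact test, adjusted p = 1.16e-09) and CHT025 (262; 6.66e-10), and intracellular protein transport genes in CHT025 (112 of 143; 3.67e-09). Of the genes of the cytosolic large ribosomal subunit, 114 of 142 were lower in CHT025 (8.78e-39) and 130 in WFYT025 (2.8e-37). On day 10 of the early season glycolysis genes rose in CHT025 (42 of 72; 2.53e-06), as did genes of flavonoid synthesis (65 of 134; 6.04e-06). Across all comparisons 2595 of 53136 term tests were called, and 2378 after quantile normalization. Genes of 1 term are not independent, so these p-values are lower than independent genes would give.

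The tests in the rest of this part were chosen after the results were seen, except the test of a response that the parents share; its value from the early season alone and the random lists were added later. Grain storage transcripts in the leaf libraries formed 2 clusters, with GluA1 at 11.9 to 111 FPKM in 24 libraries and 0.46 to 1.7 in 12. Within the 24, GluA1 and the mean of 10 prolamin and seed allergen genes had r = 0.97 (rho 0.95; permutation p = 1e-05 for each, the smallest that 100000 permutations can give, Benjamini-Hochberg 2e-05 over 2 relations), and r = 0.964 without the 2 farthest libraries. Within the 12 they had r = 0.615 (permutation p = 0.0312, Benjamini-Hochberg 0.0312) and rho 0.249 (0.434, Benjamini-Hochberg 0.434). The highest GluA1 values, 78.9 to 111 FPKM, were those of WFB on day 1 of the middle season. Of the 12 groups, 8 hold replicates of both clusters and 4 lie wholly in the higher one. RNA from developing grain may be present in the 24 libraries of the higher cluster. Whether it came in at harvest or between libraries, or whether leaves express these genes, was not tested.

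The 471 genes at least 2-fold above both parents in the hybrid on day 10 of the middle season were weighed as a pattern. The authors' scaling and a single hybrid library are argued against, since 98.9% were still called after quantile normalization and at least 96.8% without any 1 of the 3 hybrid libraries. Of the 471, 73.5% (346) changed 2-fold with day, in either direction, in a parent, against 28.4% of all genes. In the early season alone, which shares no library with the pattern, it was 59.7% against 21.7%. It was at most 28.7% in 10000 random lists of like mean expression. Those lists were not matched for how much a gene varies, and the 471 were picked for a large difference. The values therefore cannot decide whether a response to conditions at harvest that the parents share is the cause. Of the 150 genes at least 2-fold below both parents on day 1 of the early season 99 were among the 471. Independent lists would share 3.8, but the 150 were also picked for a large difference, so this does not measure chance. A difference of the hybrid itself stays open and was not tested.

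Other splits of the libraries were counted for each comparison. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05; in each such comparison 1 of the 10, the real one, gave as many genes. For day 10 against day 1 the real and the highest other values were 13216 and 1 (WFB, early), 12382 and 3 (WFB, middle), 12084 and 2 (CHT025, early), 8103 and 6 (CHT025, middle), 12639 and 1 (WFYT025, early) and 11942 and 2 (WFYT025, middle). Against WFB they were 8949 and 1, 11309 and 7, 10983 and 1, and 10288 and 3. Against CHT025 they were 7869 and 1, 13708 and 10, 6464 and 8, and 10575 and 1, in the order day 1 early, day 1 middle, day 10 early and day 10 middle.

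Against the mid-parent 1 and 1 of 100 splits, the real ones, gave as many genes as the real 11989 and 10167 on day 1 and day 10 of the middle season. The highest others were 10579 and 9050, from splits that keep 1 variety together as the hybrid. In the early season 2 and 2 of 100 did (real 7389 and 7697, highest others 10161 and 8453). Outside both parents 2 and 2 of 100 did on day 1 and day 10 of the early season (real 2272 and 1857, highest others 5803 and 5083) and 6 and 7 in the middle season (real 5437 and 4956, highest others 7815 and 6398). Apart from the real one, each split as large keeps the libraries of 1 variety together as the hybrid. In the early season that variety was a parent, and in the middle season it was a parent in 3 and 4 splits and the hybrid, with the parents mixed, in 2 and 2. This is the structure of varieties in the libraries. Only 2 and 1 such splits were drawn in the early season, against 5 and 6 in the middle season, so these shares depend on the draw. They do not settle whether chance is excluded for the mid-parent or outside both parents in either season. Among the splits that mix varieties, in the order day 1 early, day 1 middle, day 10 early and day 10 middle, the highest was 497, 1639, 380 and 393 outside both parents and 5774, 7882, 7478 and 4404 against the mid-parent, of which 7478 lies close to the real 7697. For the season 1 of 100 splits gave as many genes as the real 14348, 14001 and 14088 in WFB, CHT025 and WFYT025. The highest others were 11679, 10909 and 11078. The split that exchanges the seasons of 1 day was drawn for CHT025 only. In WFB it would give 14373, above the real 14348, so these shares too do not settle whether chance is excluded.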
